A study of Mus musculus with 4 samples.

How the data were processed

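Footpad RNA from 2 WT and 2 Tabby samples at E17.5 was measured on 2-colour Agilent oligonucleotide arrays. Per the labels, footpad RNA was extracted with Trizol, amplified and labelled with Cy3, and a pool of RNA from cultured mouse cell lines, the same for every array, was labelled with Cy5. No dyes were swapped. Per the file headers, the deposited intensity values (mean spot intensity and local background median in each channel) and the log10 ratio of Cy5 over Cy3 came from Agilent Feature Extraction 9.5.1.1, which also gave background-subtracted, dye-normalized signals and flags for outlying spots and backgrounds. The authors' deposited table of log10 values holds 25164 rows per array, with medians of 2.437, 2.42, 2.427 and 2.43. Its rows were matched to spots by feature number. Its differences between arrays correlated with those of the scanner's log ratio at r = 0.999999 over 16258 probes, and its level followed the footpad signal with slopes of 0.989 to 1.01, so its scale is log10 and its direction footpad over reference. How its level per probe was set is not given in the sources used here.

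Each array held 43451 spots, of which 1417 were controls, and 42006 different probes of 60 bases, 7 of them in 5 spots each. The files name a probe only by its array code and sequence, and do not pair it with a gene, a transcript or a position. No table that pairs these codes with genes was used here, and a table of gene symbols without sequences matched 0 of them. The planned gene lists, the planned named genes, and the check of Eda could therefore not be run, and each probe was tested by itself. For the same reason at most 2 probes per direction are named.

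The main test was fixed before the data were examined. Mean intensities were corrected with limma's normexp method (version 3.58.1 in R 4.3.3) with an offset of 50, using the local background medians, and log ratios were normalized by loess within each array with control spots given weight 0. Spots with a feature outlier flag were left out, background outlier flags were not used, and spots of a probe were averaged. Log2 ratios were turned to footpad over reference. Probes well above background in the footpad channel on both arrays of at least 1 group were tested, which left 28414 probes with values on all arrays. Tabby and WT were compared with limma's lmFit and eBayes, with Benjamini-Hochberg adjustment and a threshold of 0.05. The test had 2 residual degrees of freedom.

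The normexp model of Tabby replicate 4 was found to be distorted by 8 spots on that array. All 8 carried a background outlier flag. A second set of values was therefore made after the data were seen, in which spots with a background outlier flag in either channel (1988, 2022, 2021 and 2071 spots per array, controls included) took the median background of their array before normexp. The planned test is kept as the main one, and values from the second set are named as such.

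The rule for named probes took, per direction, probes past the threshold by size of change, and then probes of at least 2-fold change whose groups do not overlap, by smallest unadjusted p in the main test, each well above background on both arrays of the brighter group. No probe passed in the main test, so the 3 named probes come from the second part of the rule. A further higher probe that the rule gave is not reported here. For a probe not well above background on either array of a group, the fold is given as a bound. The bound is the mean of the bright group over the mean of the dim group, in the footpad channel after loess and quantile normalization of average intensities (Aquantile), with each dim array at the higher of its own value and the lowest value of a detected probe.

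Classes of probes were formed from their sequences, after the files were seen and before the groups were compared, since no genes could be named. They were motifs in a translated reading frame, the poly(A) signal and the AU-rich element. The 8 classes with at least 5 tested probes were tested with limma's camera, with a preset correlation of 0.01 and with an estimated one.

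The tests were run on simulated data with the means of the real probes and 200 changed probes, in 10 runs per fold. The spread of each simulated probe was drawn from the distribution that limma had fitted to the real probes. With the spread of the main values over 28414 probes, 0% of probes changed 2-fold and 79.2% of those changed 4-fold were called in WT against Tabby. With the spread after the background replacement, 87.8% of probes changed 1.5-fold and 99% of those changed 2-fold were called, with a mean of 8.4 and 10.4 false calls. These simulations draw all arrays with equal spread, and leave out any effect of array position. Their noise was normal and independent between probes, as limma's model assumes, so the shares hold only where that model does. The folds were added to log ratios that the offset had already shrunk at dim probes. The shares are therefore for folds of the tested values, and may be too high for folds of RNA. With 200 changed probes, the adjusted threshold is also easier to pass than with few. In the real values after the replacement, 6 probes were at least 2-fold lower and 1 higher in Tabby without overlap. The calls of that size fell 3.42-fold, 3.41-fold and 2.04-fold.

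Fixed in advance as other settings were other background corrections, the scanner's log ratio, median centring, Aquantile, the footpad channel alone, the authors' value table, other filters on dim probes, another variance model, the replicate number as a block, other thresholds, and each array left out in turn. Position on the slide followed the groups, and all arrays shared 1 slide, so no batch could be tested.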

Results

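The data collected were gene expression profiles of mouse footpads at embryonic stage E17.5, in wild-type (WT) and Tabby mice on the C57BL/6 background. Tabby mice lack ectodysplasin (Eda), a signalling ligand needed for the development of skin appendages, sweat glands among them. The footpad is the part of mouse skin that carries sweat glands. The study's stated purpose was to find targets of Eda in sweat gland development, and the comparison at this stage asks which transcripts differ between WT and Tabby footpads. There were 2 WT and 2 Tabby samples, numbered 3 and 4 in each group. The labels give the WT samples as male and the Tabby samples as mixed sex. Nothing in the labels says that the samples of a group came from separate animals, so the tests measure the spread between these samples, which may be in part technical. Each footpad RNA was hybridised in the Cy3 channel against a common pool of mouse cell line RNA in the Cy5 channel, on 4 arrays of 1 slide.

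Signal was similar across the 4 arrays. Footpad RNA gave a signal well above background at 29061 of 42006 probes in WT replicate 3, 28573 in WT replicate 4, 28238 in Tabby replicate 3 and 28574 in Tabby replicate 4. The median footpad signal over local background was 83.0 and 74.0 units on the WT arrays and 70.5 and 71.1 units on the Tabby arrays. No gene names could be given to the probes, because the files give each probe only an array code and a sequence, and no annotation or transcript sequences were used here to place them. The level of Eda itself and of the gene groups chosen for the study is therefore not reported, and the genotype labels were not checked against the mutated gene.

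Few probes passed a test between WT and Tabby footpads. In the test as it was planned, with each spot's background as measured, 0 of 28414 probes passed limma's test at an adjusted p under 0.05 in either direction. In simulated data with the spread of these values, the same test called 0% of probes changed 2-fold and 79.2% of those changed 4-fold. The count of 0 therefore says little about changes of 2-fold. When spots with an outlying local background were given the median background of their array, a step chosen after the data were seen, 7 of 28414 probes fell in Tabby and 0 rose in the same test. On these replaced values, leaving out 1 array at a time gave 4 to 14 calls, of which 1 to 6 were higher in Tabby, and 3 or 4 of the 7 probes were among them each time. There were 10 calls without WT replicate 4 (6 higher), 14 without Tabby replicate 3 (2 higher) and 4 without Tabby replicate 4 (1 higher). With all arrays, the fitted falls of the 7 probes ranged from 1.57-fold to 3.42-fold, 2 of them at probes too dim in Tabby for more than a bound. At an unadjusted p under 0.05 there were 207 probes in the planned test and 1361 after the replacement, against 1421 expected by chance. The planned count of 0 depended in part on Tabby replicate 4, where 8 spots had a local background brighter than the spot itself. The background model fitted to that array then had a mean of -243.4 units, against 10.4 to 11.6 units on the other arrays. Its log2 ratios had an interquartile range of 0.641, against 1.13 to 1.16 on the other arrays, and 1.13 after the replacement. The counts also depended on the offset added to the signals before taking logs. With an offset of 0 no probe passed, with or without the replacement. Leaving out only the 8 spots gave 4 calls, all among the 7 probes. The scanner's log ratio, which does not use that background model, gave 0 calls. The footpad channel alone gave 7 calls, 3 of them among the 7 probes, and the authors' value table gave 1, also among them. Without background subtraction, a setting fixed in advance, there were 8 calls (1 higher), 6 of them among the 7 probes.

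**Figure D1:**
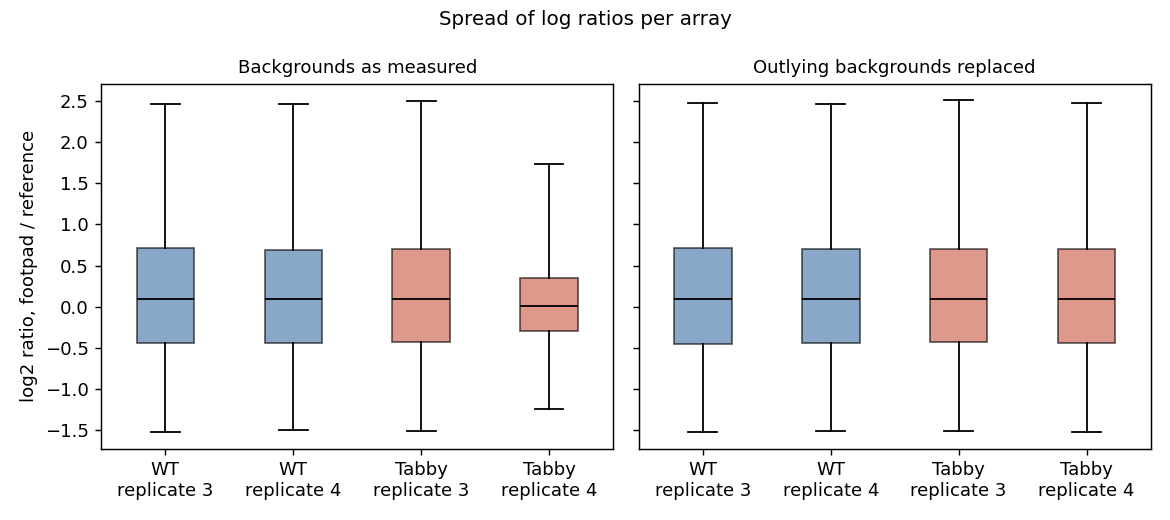
Spread of log2 ratios of footpad over reference signal on each array, with backgrounds as measured (left) and with outlying backgrounds replaced (right); boxes give the quartiles and median, and whiskers the 5th and 95th percentiles of the tested probes. The interquartile range of Tabby replicate 4 was 0.641 on the left and 1.13 on the right.

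With outlying backgrounds replaced, the probe with the smallest adjusted p was Z00036698-1, whose 60-base sequence is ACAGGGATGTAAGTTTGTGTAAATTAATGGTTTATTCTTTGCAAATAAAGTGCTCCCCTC and holds a poly(A) signal. On the same values, its log2 ratio of footpad to reference was 1.32 ± 0.0935 (SD, n = 2) in WT and -0.46 ± 0.108 (SD, n = 2) in Tabby. It fell by 1.77 on the log2 scale (SE 0.0756, 95% confidence interval -1.96 to -1.59, adjusted p = 0.00435), a 3.42-fold fall on signals with an offset of 50 added, which shrinks folds at low signal. Its log2 change was -2.61 in the scanner's log ratio (adjusted p = 0.287) and in the authors' deposited table (adjusted p = 0.136), and -2.68 in the footpad channel alone (adjusted p = 0.019). In the planned test its log2 change was -1.59 (SE 0.121, adjusted p = 0.862). The scanner software's footpad signal for this probe was 685.6 and 787 units on the WT arrays and 118.9 and 108.8 units on the Tabby arrays, while the reference signal stayed between 235.1 and 258.6 units on the 4 arrays.

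Probe Z00077373-1, with the sequence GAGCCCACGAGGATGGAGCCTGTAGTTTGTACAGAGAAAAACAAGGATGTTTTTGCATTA, was well above background on both WT arrays and on neither Tabby array. Its footpad signal was 258.9 and 378.8 units in WT and 15.1 and 7.83 units in Tabby. WT was at least 2.94-fold brighter than Tabby in the footpad channel with outlying backgrounds replaced. The test of its log ratio gave an adjusted p of 0.0249, and the authors' deposited table gave an adjusted p of 0.0302. The scanner's log ratio gave 0.0557 and the footpad channel alone 0.123, neither of which passed. The table's differences between arrays follow the scanner's log ratio, with 17760 probes tested against 28414, so its pass is not separate support. In the planned values the bound on the fold of Z00077373-1 was 2.71-fold (adjusted p = 0.862). This probe was not well above background in the reference RNA on any array, so its log ratio rests on a dim reference signal. On the Tabby arrays both channels were dim, and the offset added to the signals shrinks such log ratios. With outlying backgrounds replaced, the Tabby log ratios were -0.0044 and 0.0135 (SD 0.0127, n = 2), against an SD of 0.27 (n = 2) in WT. The Tabby SD therefore cannot be read as the spread between samples, and the adjusted p of 0.0249 rests in part on it. In all, 2 of the 7 probes that fell were not well above background on either Tabby array, and the other 5 were detected on both.

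**Figure D2:**
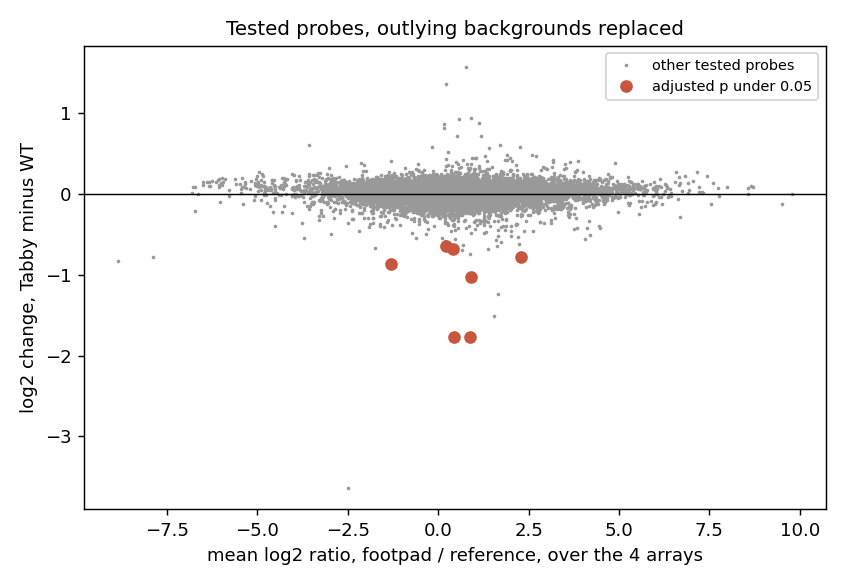
Log2 change between Tabby and WT (vertical axis) against the mean log2 ratio of footpad over reference signal (horizontal axis) for the 28414 tested probes, with outlying backgrounds replaced. The 7 probes with an adjusted p under 0.05 (larger points) all lie below 0, with log2 changes from -1.77 to -0.65.

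No probe rose in Tabby in either of these tests. One of the higher probes that the naming rule gave, Z00076581-1, has the sequence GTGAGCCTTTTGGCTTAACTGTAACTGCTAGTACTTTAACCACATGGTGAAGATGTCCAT and passed neither test. Its log2 change was 1.10 in the planned test (SE 0.119, adjusted p = 0.862) and 0.60 after the replacement (SE 0.223, adjusted p = 1). Its planned value on Tabby replicate 4 was raised by the distorted background of that array. After the replacement, the log2 ratio of Z00076581-1 was -2.89 in Tabby replicate 3 and -3.67 in Tabby replicate 4, and its WT mean was -3.88 ± 0.0738 (SD, n = 2).

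**Figure D3:**
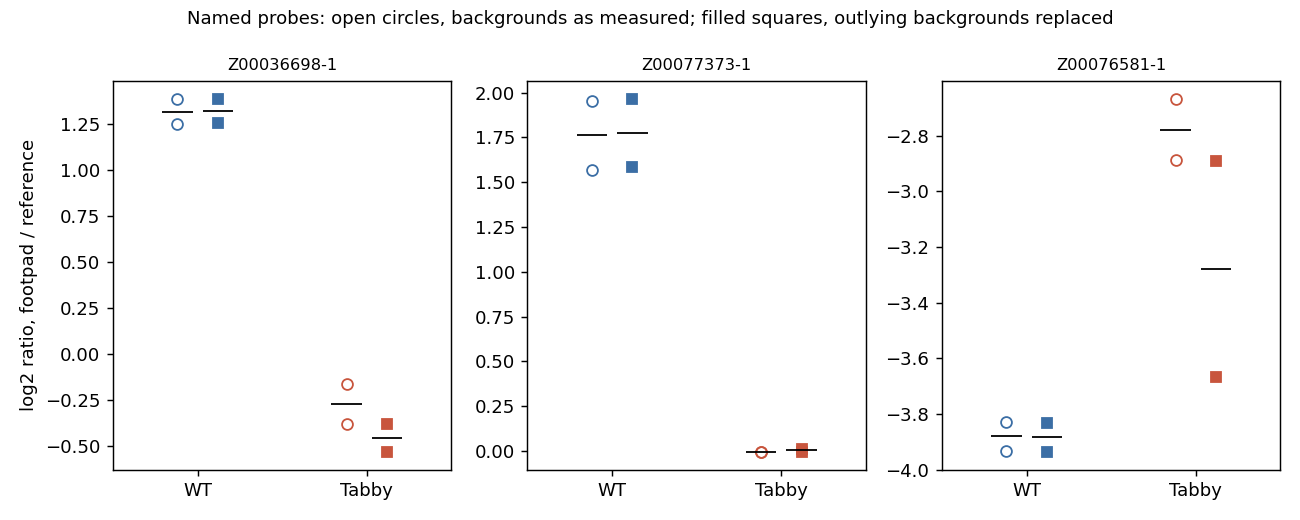
Log2 ratio of footpad over reference signal (vertical axis) on each array for the 3 named probes, in WT (blue) and Tabby (red); open circles are values with backgrounds as measured, filled squares are values with outlying backgrounds replaced, and horizontal bars are means of 2 arrays. The WT and Tabby points of Z00036698-1 and Z00077373-1 lie apart in both, while Tabby replicate 4 moves down after the replacement for Z00076581-1.

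Across all tested probes, WT and Tabby arrays were compared with the other splits of the 4 arrays. After the replacement, 31.9% of the tested probes had WT and Tabby arrays that did not overlap, where chance gives 33.3%. Among them, 16 probes were at least 1.5-fold lower and 9 at least 1.5-fold higher in Tabby, against 275 and 262 in the planned values and 202 and 78 in the footpad channel alone. The other splits of the arrays gave more on the replaced values, with 48 and 3 probes for replicate 3 against replicate 4, and 32 and 16 for WT replicate 3 and Tabby replicate 4 against the rest. The same splits gave fewer in all than WT against Tabby did in the planned values (443 and 86, and 50 and 436) and in the footpad channel alone (118 and 58, and 86 and 103). After the replacement, the log2 ratios of the 2 WT arrays correlated at r = 0.9942 across probes, which are not independent replicates. Those of the 2 Tabby arrays correlated at r = 0.9952, and WT arrays with Tabby arrays at 0.9945 to 0.9956. In the planned values the WT pair gave 0.9942, the Tabby pair 0.9619, and WT with Tabby arrays 0.9587 to 0.9955. In the footpad channel, 177 probes were well above background on both WT arrays and neither Tabby array, and 46 the other way round, while WT replicate 3 and Tabby replicate 4 against the rest gave 191 and 60. The 13 pairs of tested probes with identical sequences gave log2 changes that differed by a median of 0.0321 after the replacement. All 4 arrays came from 1 slide and 1 scan, with WT and Tabby in separate positions, so position and genotype cannot be told apart. Sex, given as male for WT and mixed for Tabby, also follows the groups and cannot be told apart from genotype. The number of arrays limits the precision of every value.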

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

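All tests in this part were chosen after the result was seen, except the count of calls in the reference channel and the test of probes detected on the Tabby arrays alone, which were fixed before their values were seen.

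On Tabby replicate 4, 8 spots were dimmer than their own local footpad background, and on the WT arrays 0 spots were. The local background reached 10714 units at these spots against a median of 41 units on that array. Its log2 ratios had an interquartile range of 0.6414 in the planned values. A candidate explanation is that these spots alone distorted the background model, since the interquartile range was 1.129 once they were left out, close to the 1.131 to 1.158 of the other arrays. A weaker hybridisation is argued against by the median net footpad signal of 71.08 units, within the 70.48 to 82.98 units of the other arrays. The genotype is argued against by the other Tabby array, whose interquartile range of 1.137 lay within that of the WT arrays.

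With outlying backgrounds replaced, 7 probes were lower in Tabby and 0 higher. A change of the reference RNA is argued against at 4 of the probes by the footpad channel alone, in which all 7 fell by more than the reference moved. The median log2 change of the 7 was -2.1, against 0.0196 in the reference channel. At the other 3 the reference was too dim to show whether it moved. The reference signal of Z00077373-1, for example, was 3.91 and 5.85 units on the WT arrays and 13.0 and 7.93 units on the Tabby arrays. As a test of slide position acting on both channels, calls were counted in the reference channel, which holds the same RNA on every array. There were 0 among 30036 probes by limma's test, with 1564 at an unadjusted p under 0.05. That test covered 4 of the 7 probes, and the other 3 were too dim in the reference. It cannot decide on slide position, because an effect alike on both channels cancels in the log ratios that gave the 7 calls. The footpad channel alone also called only 3 of the 7 probes, so a lack of calls in 1 channel is weak evidence. An effect of position on the footpad channel alone stays open, since position follows genotype. The sex of the embryos and the genotype also stay open: no probe has a known chromosome, and the largest bound among the 46 probes detected on the Tabby arrays alone was 1.17-fold, which decides nothing without knowing whether an X-inactivation transcript is on the array. The 4 arrays allow 3 splits, of which 1, the real one, gave 7 calls, and the highest of the others gave 0. They are too few for a share under 0.05.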

How the results depend on the processing

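The planned test gave 0 changed probes. It also gave 0 with a normexp offset of 0, the scanner log ratio (also, added later, with trend and robust variance), median centring, Aquantile (which cannot change log ratios), either other filter, the other variance model and both other thresholds. Testing all probes one by one was the main test itself. Without background subtraction 8 changed, 1 higher and 7 lower, with 6 of the 8 among the 7 probes that follow. The footpad channel alone gave 7, all lower (3 of them among those 7 probes), and the authors' value table gave 1, lower. Leaving out each array, with the lone array assumed to vary like the other group, gave 0 to 11538 changed, 0 to 3776 higher and 0 to 7762 lower. The highest came without Tabby replicate 3, which leaves only the distorted Tabby array, and without Tabby replicate 4 there were 4 (1 higher, 3 lower). Causes of the other differences were not tested. Median centring moved the median log2 change of all tested probes to -0.385.

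The following were chosen after seeing the data. Replacing outlying backgrounds gave 7 changed, all lower, leaving those spots out the same 7, and leaving out only the 8 dim spots 4 of the 7. On the replaced values, no filter, trend with robust variance and a 1.5-fold minimum kept all 7. Requiring detection in both channels on all arrays gave 2, both lower, and tested 4 of the 7. An offset of 0 gave 0, and an adjusted p under 0.10 gave 9, 1 of them higher. Leaving out each array gave 4 to 14 changed, 1 to 6 higher and 3 to 12 lower, with 3 or 4 of the 7 called each time. There were 10 without WT replicate 4 (6 higher), 14 without Tabby replicate 3 and 4 without Tabby replicate 4.

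The replicate block fit gave 0 in the planned values and 3, all lower, after the replacement. Same-numbered arrays did not deviate together (correlation across probes 0.0889 and -0.0166), and 2 pairs share only a number.

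Of the settings that tested Z00036698-1, 14 gave other values than the planned ones, and the rest could change only the test. It was lower in Tabby in all 14 (log2 change -2.68 to -1.48) and past the threshold in 7. Z00077373-1, with only a bound in Tabby, was past it in 7. Z00076581-1 ranged from 0.60 to 1.45. It was past the threshold in 2, without Tabby replicate 3 (log2 change 1.21) and without Tabby replicate 4 (0.99). Both leave 1 Tabby array, assumed to vary like the WT arrays, so passing there says little about a probe. The same 2 settings are among the 7 of each other named probe. Gene lists and Eda were not run, since no probe has a gene name. Low signal over background limits probes dim in 1 group.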

Other observations

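The tests of hypotheses in this part were chosen after the values were seen. One hypothesis was that probes lower in Tabby may be those with footpad-enriched transcripts. Among the 16 probes at least 1.5-fold lower without overlap, 6 (37.5%) were at least 2-fold brighter in footpad than in the reference, against 18% of the others, an odds ratio of 2.74 (two-sided Fisher's exact test, p = 0.0527, over probes that are not independent replicates). Footpad was Cy3 and reference Cy5 on every array, so brighter in footpad cannot be separated from a dye effect. Both measures came from the same log ratios. Other splits of the arrays gave larger sets, with 48 probes in 1 direction (3 in the other) and 32 (16 in the other). The test was not run on those sets. It missed the threshold and leaves the hypothesis open.

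A second hypothesis was that Tabby footpads may have lost transcripts that WT footpads express. The 177 probes detected on the WT arrays alone cannot decide it. Another split of the arrays, WT replicate 3 and Tabby replicate 4 against the rest, gave 191. Both pairs hold WT replicate 3, which had the most probes well above background (29061). With 3 splits, no count can reach a share under 0.05.

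Of 8 classes of probes defined by sequence, 0 passed camera's test after the background replacement (smallest adjusted p = 0.0922, for cysteine-rich reading frames, with 0.787 under an estimated correlation). In the planned values 1 class, proline-rich reading frames, passed (adjusted p = 0.00605), and it did not with an estimated correlation (adjusted p = 0.691) or after the replacement (adjusted p = 0.244). That motif was found in 60 probes as printed and in 53 on the opposite strand, so most of its matches need not be coding. The poly(A) signal was found in 4160 probes as printed and 2321 on the opposite strand. Over its 3094 tested probes the adjusted p was 0.809 in the planned values and 0.963 after the replacement, and 0.918 and 0.982 with an estimated correlation. The zinc finger linker, in 17 probes as printed and 1 on the opposite strand, had the same 4 adjusted p over 13 tested probes.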
